A study of Mus musculus with 6 samples.

How the data were processed

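Lung fibroblasts of untreated collagen reporter mice (Col-GFP) were profiled before and after transfer into the airways of host mice that had received bleomycin, a lung-injuring drug, 7 days earlier. Expression was measured by 3' SAGE, in which each transcript is represented by a short tag near its 3' end, from cDNA amplified by PCR, per the labels' protocols. The submitters' processing notes name BWA 0.6.2 and the mouse build mm9. The enzyme that anchors the tags, the rule that assigned tags to genes and the use of strand are not given in the sources used here.

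The authors deposited 1 table of 24408 gene symbols in CPM (tags scaled to 1000000 per library) for 6 libraries, per the file headers. Each column sums to 1000000 over the listed genes, so the CPM values count tags per 1000000 assigned tags. The deposited CPM values step in equal units, and 100% of them were whole multiples of the smallest value in their library within 0.001. The tag counts recovered in this way gave the depth of each library, which ran from 4448065 tags for Day 4 to 6175334 for Day 2. A value of 10 CPM in the Day 4 library has a 95% Poisson interval of 7.19 to 13.3 CPM. PCR copies were not marked by molecular identifiers, so intervals and floors cover counting error only. In 25 rows the symbol had been turned into a date, and the symbol in the row's transcript title was used (Sept4, for example). A gene listed at 0 in every library may lack a tag that the counting could use.

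The groups were taken from the sample titles, with 1 library each: Untreated, Day 2, Day 4, Day 7, Acta2 low and Acta2 high. Because no group has a second library, no spread between samples could be estimated, and no p-value across genes is given. The rules were fixed before the data were examined. For each of 6 comparisons the difference of log2(CPM + 1) was taken over measured genes, those with a mean of at least 10 CPM over the compared libraries. A gene counted as higher or lower when the difference reached 2, which is 4-fold on this scale; the pseudocount of 1 understates the change of low genes. The named genes were 7 anchor genes, the 5 genes with the largest differences each way among named symbols with a mean of at least 50 CPM (3 for Day 4 against Day 2 and for Day 7 against Day 4), and up to 4 members of each gene list called apart. The values of some genes that this rule names are not reported here.

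For the 27 gene lists, the median log2 difference of the measured members was placed among 10000 random lists of the same size, drawn with replacement within 20 bins of mean log2 expression. A list was called apart below the 2.5th or above the 97.5th percentile, and lists with fewer than 3 measured members were not placed. These percentiles describe these libraries only. Of 574 list members in the table, 9 stand in 2 lists: C3, Dcn, Krt8, Krt18, Krt19, Npnt, Postn, Sfrp4 and Wnt2. Ratios of CPM carry exact conditional (Clopper-Pearson) 95% intervals of the tag counts. A gene at 0 tags was set to a floor of 3 tags in its library, and its ratio is given as a bound.

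The median of all measured genes differed between libraries by 0.66 log2 for Day 2, 0.31 for Day 4 and 0.39 for Day 7 against Untreated, by -0.14 for Acta2 high against Acta2 low, by -0.35 for Day 4 against Day 2 and by 0.07 for Day 7 against Day 4. Folds of single genes are therefore given relative to the median gene, which is the CPM ratio divided by the fold of that shift, and list medians are given as their distance from it.

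On simulated libraries with the real depths and means and 200 changed genes, the size rule called 98.0% of the 8-fold genes and 32.0% of the genes at exactly 4-fold for Day 2 against Untreated, where 4257 genes were measured. It called 0 of 4063 unchanged genes there. These simulations hold counting noise only, so that 0 is no rate of false calls between samples. Among the 4256 genes measured for that comparison in the real table, 3.5% of 200 random lists of 15 genes were called apart, and 72.0% of 100 such lists after every member was raised by 1 log2.

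The alternatives planned beforehand were pseudocounts of 5 and 0.1 CPM, no filter on low values, median-ratio scaling, CPM recomputed without the 100 most abundant genes, and an exact two-sided binomial test of the recovered tags with Benjamini-Hochberg adjustment at 0.05 added to the size rule. That last test compares 2 libraries, not the conditions. A 2-fold rule, a run without genes that share a tag sequence with 100 or more other genes, and a run with genes at 0 tags set to the floor were added after seeing the data. For the shared tags, the transcripts of the GENCODE annotation were searched for the 14 bases that follow and include each CATG, the site of the enzyme most SAGE protocols use; its use here is an assumption. A transcript could be searched for 20259 rows, 83.0% of the table. That annotation belongs to a later mouse build than mm9, so no coordinates are printed. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.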

Results

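Donor lung fibroblasts carrying a collagen reporter (Col-GFP) were profiled by 3' SAGE before transfer (Untreated) and after recovery from injured host lungs on days 2, 4 and 7 after transfer. A further pair of libraries held transferred cells of a double reporter strain, sorted by low or high signal of Acta2, the gene of smooth muscle actin. The day of that sort is not given in the labels. Each of the 6 groups is 1 library, so no difference below has a replicate check and every interval is a counting interval. The libraries held 5470701 tags (Untreated), 6175334 (Day 2), 4448065 (Day 4), 5853425 (Day 7), 5090808 (Acta2 low) and 5008311 (Acta2 high), with 12575 to 13448 genes detected. Counts of genes past 4-fold use the log2 differences as they stand, and folds of single genes are relative to the median gene. The 10 most abundant genes took 49.4% of the Untreated tags, 17.4% of them from Gsn, and 24.0% of the Day 2 tags. A set of 45 genes led by Zyg11b and Luc7l2, picked after their values were seen, took 9.74% of the tags in Day 2, 13.3% in Day 4, 13.2% in Acta2 low and 9.10% in Acta2 high, against 0.657% in Untreated and 1.44% in Day 7.

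Against the untreated cells, fibroblasts recovered 2 days after transfer carried more transcripts of cell division, cytokine, glycolysis and ribosomal genes, and far fewer of the genes typical of alveolar and adventitial fibroblasts. Inhba, which encodes an activin subunit, stood at 845.9 CPM against 2.93, 183-fold higher relative to the median gene (95% interval 113 to 321). Timp1, an inhibitor of matrix proteases, reached 8712 CPM against 111.1, and Fst, an activin antagonist, 218.8 against 2.38. Cxcl3, a neutrophil chemokine, and the histone gene Hist1h2ao were 66.6-fold (34.9 to 146) and 67.0-fold (33.9 to 156) higher. Of 4256 measured genes, 578 were at least 4-fold higher at Day 2 and 200 at least 4-fold lower.

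Of 39 cell cycle genes in the table, 16 were measured at Day 2, and their median lay 3.51 log2 above that of all measured genes (100th percentile of matched random lists). All 16 were at least 4-fold higher, but a gene near 0 in Untreated is measured only if it is high at Day 2, so that count follows in part from the filter; without it the list stayed at the 100th percentile. Cdk1, the mitotic kinase, stood at 51.8 CPM against 0.731, and Mcm5, a helicase subunit of DNA replication, at 81.3 against 1.10. Tk1 and Ccnb1 had 1 tag each in Untreated, which gives ratios of 173 (30.7 to 6835) and 102 (18.1 to 4061). The cytokine and chemokine list was 1.54 above (99.93rd percentile), with 8 of 15 measured members at least 4-fold higher and 7 within 4-fold. Ccl2, a monocyte chemokine, was 23.6-fold higher (19.8 to 28.3), Ccl7 15.8-fold (14.1 to 17.7) and Cxcl2 21.3-fold (14.1 to 33.8). Cxcl5 had no tag in Untreated and was at least 87.5-fold higher. Glycolysis and hypoxia genes lay 1.09 above (99.44th percentile), with 3 of 13 members past 4-fold, among them Pkm2 at 313 against 49.0 CPM and Ldha at 1261 against 226.5. Pgk1 was 2.57-fold higher (2.16 to 3.07). Of 30 measured ribosomal protein genes, 26 were at least 4-fold higher before the shift of the median gene is taken out. Rps6 was among them, at 1159 against 75.3 CPM. The list lay 1.87 above the median gene (100th percentile), which is under 4-fold.

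The alveolar fibroblast list lay 4.41 log2 below the median gene at Day 2 (percentile 0.0), with 14 of 20 measured members at least 4-fold lower and 6 within 4-fold. Mettl7a1 was 331-fold lower (232 to 492), at 4.86 against 1021 CPM, and Inmt, a methyltransferase abundant in lung, 170.5-fold lower (150.5 to 194). Fmo2, a lung monooxygenase, was 87.6-fold lower (77.7 to 99.1). Slc7a10 had 1 tag at Day 2 against 303, a ratio of 539 (96.1 to 21370). The adventitial list lay 3.42 below (percentile 0.0), with 9 of 15 members at least 4-fold lower, among them Gsn at 2260 against 173857 CPM, Clec3b at 11.7 against 719.5, Pi16 at 21.1 against 1002 and Igfbp6 at 107.5 against 3384. Sept4, a septin outside the lists, was 129-fold lower (117 to 142).

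Immediate early genes, which respond within minutes to stimulation or tissue dissociation, lay 2.61 below the median gene at Day 2 (percentile 0.0): 10 of 21 were at least 4-fold lower and 1 was higher. Fos stood at 2712 CPM against 53786, Zfp36 at 2942 against 24493, Ier2 at 891.6 against 6286 and Atf3 at 23.5 against 281.9. Complement genes lay 2.71 below (percentile 0.0), with 6 of 10 past 4-fold, including Serping1 (24.9-fold lower, 24.2 to 25.7), C1s and C2. The interferon list lay 1.34 below (0.34th percentile), but its members went both ways. Before the shift of the median gene is taken out, 1 of 10 was past 4-fold lower, Ifi27l2a, at 26.9 against 209.5 CPM. Relative to the median gene H2-D1, H2-K1 and Irf1 were 5.08-, 4.80- and 4.48-fold lower. In CPM 4 of 10 members were higher at Day 2, among them Ifit3 (32.9 against 14.4), Bst2 (194.6 against 107.1) and Irf7 (22.0 against 13.0). Matrix proteases and their inhibitors lay 1.14 below (0.26th percentile) and went both ways, with Timp3 (10.6-fold lower, 9.81 to 11.5), Mmp2, Mmp11 and Timp2 on the lower side and Timp1 on the higher.

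Among the anchor genes at Day 2, Acta2 stood at 137 CPM against 8.77, 9.90-fold higher (7.40 to 13.5), Tnc, a matrix glycoprotein of wounds, was 34.0-fold higher (20.5 to 61.0) and Cthrc1, a secreted protein of activated fibroblasts, 63.8-fold higher (30.8 to 159). Col1a1 was 1.59-fold higher (1.502 to 1.679). Col3a1 did not differ from the median gene, at a ratio of 0.988 (0.926 to 1.06); its CPM was higher, and the direction turns under median-ratio scaling. Gli1, a Hedgehog target, had 13 tags against 39, and Mki67, a proliferation marker, 19 against 0, which is at least 3.56-fold higher. Scaling decides the balance of the counts for this comparison: 302 genes were higher and 313 lower under median-ratio scaling, and 446 and 522 when CPM left out the 100 most abundant genes. The interferon list moved to the 71.3rd percentile without the filter on low values and to the 58.7th without the 100 most abundant genes, so its place depends on those choices; without the filter the glycolysis and protease calls were lost as well, at the 89.6th and 27.0th percentiles.

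By day 4 the matrix and contractile genes stood apart on the higher side. The cytokine list (85.58th percentile) and the glycolysis and hypoxia list (93.58th), both high at Day 2, were no longer apart. Even so, 4 of 13 measured cytokine members were still at least 4-fold higher than in Untreated, among them Ccl2 (513.5 against 23.6 CPM) and Ccl7 (738.5 against 58.1). Spp1, which encodes the secreted phosphoprotein osteopontin, reached 12975 CPM against 7.49 in Untreated, 1397-fold higher relative to the median gene (1030 to 1947), and Cthrc1 reached 969.9 against 1.28 CPM, 612-fold higher (297 to 1522). Timp1, Fst and S100a4, a calcium-binding protein of motile cells, were 71.0-fold (65.5 to 77.0), 99.3-fold (57.9 to 187) and 73.2-fold (59.8 to 90.6) higher. Of 3933 measured genes, 393 were at least 4-fold higher and 201 at least 4-fold lower. Without the shared-tag genes, 322 were higher and 189 lower.

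The fibrillar and interstitial matrix list lay 1.78 log2 above the median gene at Day 4 (99.99th percentile): 13 of 25 measured members were at least 4-fold higher, 1 lower and 11 within 4-fold. Col1a1 stood at 3560 CPM, 9.26-fold higher (8.81 to 9.74), Col3a1 was 3.15-fold higher (2.97 to 3.35) and Tnc 34.9-fold (20.99 to 62.87). Postn, a matricellular protein, had no tag in Untreated and was at least 60.5-fold higher, and Col8a1 had 98 tags against 1, a ratio of 97.3 (17.1 to 3881). The contractile list lay 1.59 above (99.85th percentile), with 6 of 15 members at least 4-fold higher. Acta2 was 32.2-fold higher (24.2 to 43.9) at 350.5 CPM, Tagln 5.83-fold (4.86 to 7.03), and Tpm2 and Actg2, with 2 tags each in Untreated, had ratios of 201 (55.3 to 1665) and 99.8 (27.3 to 829).

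Cell cycle genes remained high at Day 4, 3.61 above the median gene (100th percentile) with 15 of the 16 measured members past 4-fold, Cdk1, Ccnb1, Tk1 and Ube2c among them; Mki67 had 20 tags against 0. Ribosomal protein genes lay 1.57 above (99.99th percentile), with 14 of 30 past 4-fold, among them Rps6, Rpl32 and Rpl23. Of the 6 lists that were low at Day 2, 5 were low here: alveolar 3.75 below with 15 of 20 past 4-fold, adventitial 3.52 below with 9 of 15, complement 3.13 below with 7 of 10 and immediate early 2.27 below with 10 of 21, all at percentile 0.0, and interferon 1.296 below with 3 of 9 (0.62nd percentile); the protease list was not apart (0.39 below, 8.62nd percentile). Inmt was 413-fold lower (319 to 544), Ces1d, a carboxylesterase, 211-fold (111 to 462), Gsn 244-fold (236 to 252), Pcolce2 62.0-fold (54.6 to 70.8), and Mettl7a1, Sept4, Fmo2, Clec3b and Pi16 between 102 and 375-fold. Egr1, Fos, Ier2 and Zfp36 were 19.4- to 29.3-fold lower, Serping1 33.6-fold (32.1 to 35.1), C1s 23.2-fold and C4b 16.8-fold. H2-K1 was 11.7-fold lower (6.64 to 22.5), ahead of Ifi27l2a, H2-D1 and Irf1. Gli1 had 19 tags against 39. Under median-ratio scaling 303 genes were higher and 267 lower, and without the 100 most abundant genes 438 and 457.

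**Figure D1:**
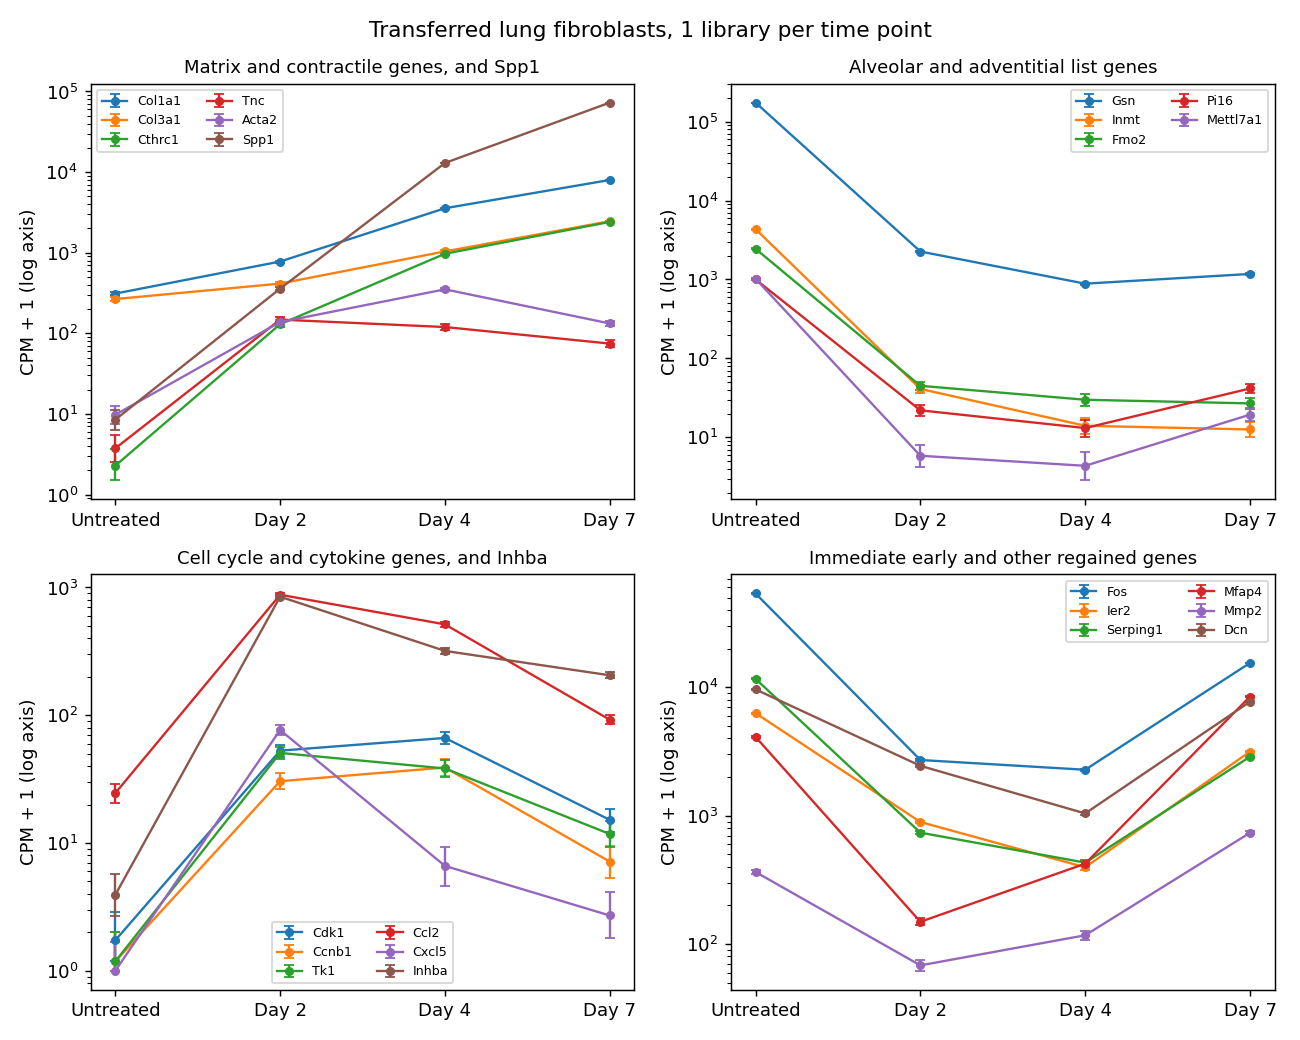
CPM + 1 on a log axis of named genes in the Untreated, Day 2, Day 4 and Day 7 libraries (1 library each; bars are 95% Poisson intervals of the tag counts, lines join libraries). Spp1 goes from 7.49 CPM in Untreated to 72790 at Day 7, Inmt from 4343 to 11.6, and Fos from 53786 through 2277 at Day 4 to 15482.

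At Day 7 the matrix genes were higher still, and Wnt pathway genes were apart. Spp1 took 72790 CPM, 7436-fold higher than in Untreated relative to the median gene (5481 to 10363), and Cthrc1 2411 CPM, 1443-fold higher (700 to 3589). Grem1, a BMP antagonist, and Acan, the cartilage proteoglycan aggrecan, had 1 tag each in Untreated and 1213 and 617 at Day 7, ratios of 868 (155.5 to 34312) and 441.5 (79.0 to 17467). Ptn, the growth factor pleiotrophin, was 91.0-fold higher (38.8 to 281). Of 4017 measured genes, 199 were at least 4-fold higher and 133 at least 4-fold lower.

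The matrix list lay 1.97 log2 above the median gene at Day 7 (100th percentile), with 15 of 25 members at least 4-fold higher, none lower and 10 within 4-fold. Col1a1 reached 7988 CPM, 19.7-fold higher (18.8 to 20.7), Col3a1 2457 CPM, 7.09-fold (6.72 to 7.49), and Lum 747.1 against 21.8 CPM. Tnc was 20.6-fold higher (12.3 to 37.1), Postn at least 128-fold, and Col8a1 had 349 tags against 1, a ratio of 249.7 (44.5 to 9892). The Wnt list lay 1.34 above (99.98th percentile), with 5 of 10 members past 4-fold; these included the secreted Wnt regulators Sfrp1 (16.4-fold, 14.4 to 18.7) and Sfrp2 (28.8-fold, 14.4 to 67.3), with Wisp1 and Nkd2 at 10.4-fold and 8.59-fold. Acta2 was 11.5-fold higher (8.57 to 15.7) at 131.5 CPM. The contractile list was not apart (91.98th percentile), although 7 of its 15 members were past 4-fold, and it reached the 98.6th percentile without the filter. Cell cycle genes had 5 measured members, 1.53 above (99.72nd percentile): Cenpa was 4.65-fold higher (2.96 to 7.66), Ccnd1 3.22-fold, Stmn1 3.05-fold and Mcm2 2.81-fold. The filter left out members near 0 in Untreated, among them Cdk1, at 14.2 CPM against 0.731, and Tk1, at 10.8 against 0.183. Mki67 had 2 tags against 0, too few for a fold. Ribosomal protein genes lay 1.04 above (100th percentile), with 1 of 30 past 4-fold, Rps4x; Rpl23, Rps24 and Rpl3 were 3.07-, 2.91- and 2.87-fold higher. Gli1, at 12.5 against 7.13 CPM, had a ratio of 1.34 (0.896 to 2.03).

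Alveolar and adventitial genes remained low at Day 7, 3.08 and 2.94 log2 below the median gene (both percentile 0.0), with 13 of 20 and 11 of 18 members past 4-fold; 1 alveolar gene was past 4-fold on the higher side. Inmt stood at 11.6 CPM, 488-fold lower (385 to 629), Gsn was 193-fold lower (189 to 198), Pcolce2 127-fold (109 to 149), Fmo2 123-fold (105 to 145) and Hsd11b1, an enzyme that activates glucocorticoids, 97.2-fold (83.8 to 114). Mettl7a1, Slc7a10, Clec3b and Pi16 were 32.2- to 106-fold lower. Complement genes lay 2.14 below (percentile 0.0) with 3 of 10 past 4-fold, C3 and Serping1 among them. Immediate early genes lay 0.62 below (0.73rd percentile), with 1 of 21 past 4-fold before the shift of the median gene is taken out, Socs3 (7.70-fold lower, 7.08 to 8.38); relative to the median gene Atf3, Egr1 and Zfp36 were 4.75- to 5.06-fold lower. The pericyte markers (97.69th percentile, 4 measured) were higher at the median through Postn and Lmcd1, while Fgfr4, at 1.88 against 28.2 CPM, was past 4-fold lower and Kcnj8, at 32.1 against 32.0 CPM, turns direction with the scaling, and the mesothelial markers (0.2nd percentile, 3 measured) were lower through C3 and Upk1b, with Slpi at 22.2 against 15.4 CPM. The pericyte call was lost with a pseudocount of 0.1 CPM (97.2nd percentile). Under median-ratio scaling, 137 genes were higher and 168 lower, and without the 100 most abundant genes 276 and 231.

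The 3 time points share the Untreated library. Of genes measured in both, 308 were at least 4-fold higher at both Day 2 and Day 4 and 160 lower, where independent lists would share 47.4 and 10.3. Day 2 and Day 7 shared 83 higher (16.7 for independent lists) and 103 lower (7.0), and Day 4 and Day 7 shared 112 higher (13.7) and 113 lower (7.1). In 20 simulations of unchanged libraries the mean overlap was 0.0, but these hold counting noise only, under which the size rule calls no gene, and give no baseline for a shared control. The single control library cannot be split, so part of the excess may come from it. Fmod, a collagen-binding proteoglycan, and Pdgfrl, the 2 genes at least 4-fold lower at Day 2 and higher at Day 7, were named after their values were seen.

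From Day 2 to Day 4, matrix transcripts went on to higher levels while cytokine transcripts were lower. Spp1 was 46.2-fold higher at Day 4 relative to the median gene (44.3 to 48.3), S100a4 11.3-fold (10.6 to 12.1) and Cthrc1 9.59-fold (8.89 to 10.4). Sod2, a mitochondrial superoxide dismutase, Saa3, an acute-phase protein, and Odc1, an enzyme of polyamine synthesis, were 4.46-fold (4.11 to 4.84), 4.16-fold (3.65 to 4.76) and 3.91-fold (3.63 to 4.22) lower. The matrix list lay 1.44 above the median gene (100th percentile), with 5 of 27 members past 4-fold, including Postn, Fn1 and Sparc. Wnt genes (1.07 above, 100th percentile; Sfrp1, Nkd2, Fzd2, Dkk3), proteases (0.69 above, 99.99th; Mmp23, Mmp2, Mmp10, Mmp14), contractile genes (0.56 above, 99.91st; Tpm2, Actg2, Myl9 and Acta2 at 3.26-fold, 2.99 to 3.55) and collagen processing genes (0.40 above, 99.88th; Fkbp7, Bmp1, Serpinh1, P4ha2) were apart on the higher side, mostly with members within 4-fold. Cytokines lay 0.72 below (percentile 0.0), with 2 of 15 past 4-fold, Cxcl5 and Saa3; Cxcl1 was 2.39-fold lower (2.31 to 2.47) and Ccl11 2.26-fold.

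The interferon list lay 0.50 below at Day 4 against Day 2 (0.78th percentile; Ifit3, Bst2, Irf7, Psmb8), the TGF-beta list 0.39 below (0.8th; Il11, Inhba, Skil, Cyr61), the adventitial list 0.40 below (1.5th; Has1, Gsn, Dcn, Pcolce2) and ribosomal protein genes 0.18 below (2.13th; Rpl18 and Rps10). Without the filter the TGF-beta and adventitial lists turned to the 72.5th and 77.4th percentiles, and the ribosomal call was lost at the 6.67th. Col1a1 and Col3a1 were 5.84-fold (5.65 to 6.03) and 3.19-fold (3.04 to 3.35) higher, Tnc did not differ from the median gene at 1.03 (0.922 to 1.15) and turns direction with the scaling, and Gli1 and Mki67 had 19 and 20 tags against 13 and 19. Of 4259 measured genes 13 were at least 4-fold higher and 11 lower; under median-ratio scaling 21 were higher and 5 lower, and without the 100 most abundant genes 34 and 12.

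From Day 4 to Day 7 cell cycle transcripts were lower, and several groups that had been low after transfer were higher. Mfap4, a microfibril protein, stood at 8462 against 421.5 CPM, 19.2-fold higher (18.3 to 20.1), with Lum, a collagen-binding proteoglycan, 16.5-fold (14.3 to 19.2) and Pltp, a phospholipid transfer protein, 16.6-fold (12.03 to 23.47). Mt2, a metallothionein, was 20.4-fold lower (19.3 to 21.7). Nol9 and H2-T3, 20.7-fold and 20.1-fold lower, belong to the set of 45 genes described above, and the transcript of H2-T3 holds a tag sequence shared with more than 100 genes. Of 4132 measured genes 92 were at least 4-fold higher and 92 lower; without genes that hold such shared tags the lower count was 51.

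Cell cycle genes lay 1.59 below the median gene at Day 7 against Day 4 (percentile 0.0), with 4 of 17 members past 4-fold: Rrm2, Ccnb1, Cdk1 (4.84-fold lower, 3.78 to 6.25) and Birc5. Mki67 had 2 tags against 20, a ratio of 13.8 (3.35 to 122). Glycolysis genes lay 0.77 below (0.09th percentile; Pkm2, Ndrg1, Pgk1, Pgam1), cytokines 0.64 below (0.86th; Ccl7 and Ccl2 at 6.24-fold and 5.90-fold lower, then Cxcl1 and Csf1) and ribosomal protein genes 0.62 below (1.27th; Rps6, Rpl14, Rpl32). On the higher side were complement (1.66 above, 100th percentile; Serping1 6.39-fold, 6.09 to 6.70, with C1s and Clu), immediate early (1.35 above, 100th; Ier2 7.62-fold, Fos 6.49-fold, Zfp36 5.22-fold, Klf2 4.36-fold), Wnt (1.31 above, 100th; Sfrp2, Nkd2, Fzd1, Nkd1), interferon (1.10 above, 99.92nd; Ifi27l2a, Ifit3, H2-D1, B2m), alveolar (0.98 above, 99.98th; Mfap4, Lpl, Tcf21, Mettl7a1), matrix (0.88 above, 100th; Lum, Dcn, Mfap2, Bgn), adventitial (0.60 above, 99.11th; Igfbp4, Dcn, Dpt, Pi16) and protease genes (0.51 above, 99.27th; Mmp2, Ctsk, Mmp11, Mmp14), the last lost at the 69.1st percentile without the filter.

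Acta2 was 2.79-fold lower at Day 7 than at Day 4 (2.56 to 3.05) and Tnc 1.69-fold lower (1.49 to 1.92), whereas Col1a1, Col3a1 and Cthrc1 were 2.14-, 2.26- and 2.37-fold higher and Gli1 2.79-fold higher on 73 against 19 tags (1.66 to 4.89). Among cell type markers with at least 3 measured members, pericyte markers were higher (99.92nd percentile, through Lmcd1, Kcnj8 and Postn). Mesothelial markers were lower (1.5th percentile, through Krt8 and Slpi, with C3 at 32.5 against 24.1 CPM). Epithelial markers were higher (97.77th percentile) through Scgb1a1 and Lyz1, although Krt8, which is on this list too, was lower at 6.49 against 16.4 CPM. Lyz2, a macrophage marker, had 1 tag or none in each library. The rule that assigned tags is not given, so whether Lyz1 tags include those of Lyz2 cannot be told. Scgb1a1, a club cell product, had 129 tags at Day 7 against 3 at Day 4, a ratio of 31.2 (10.4 to 153), and the epithelial call turned to the 44.3rd percentile without the filter. Sftpc, an alveolar type II cell product, stood at 20.7 CPM in Untreated, 5.51 at Day 2, 3.37 at Day 4 and 14.9 at Day 7.

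**Figure D2:**
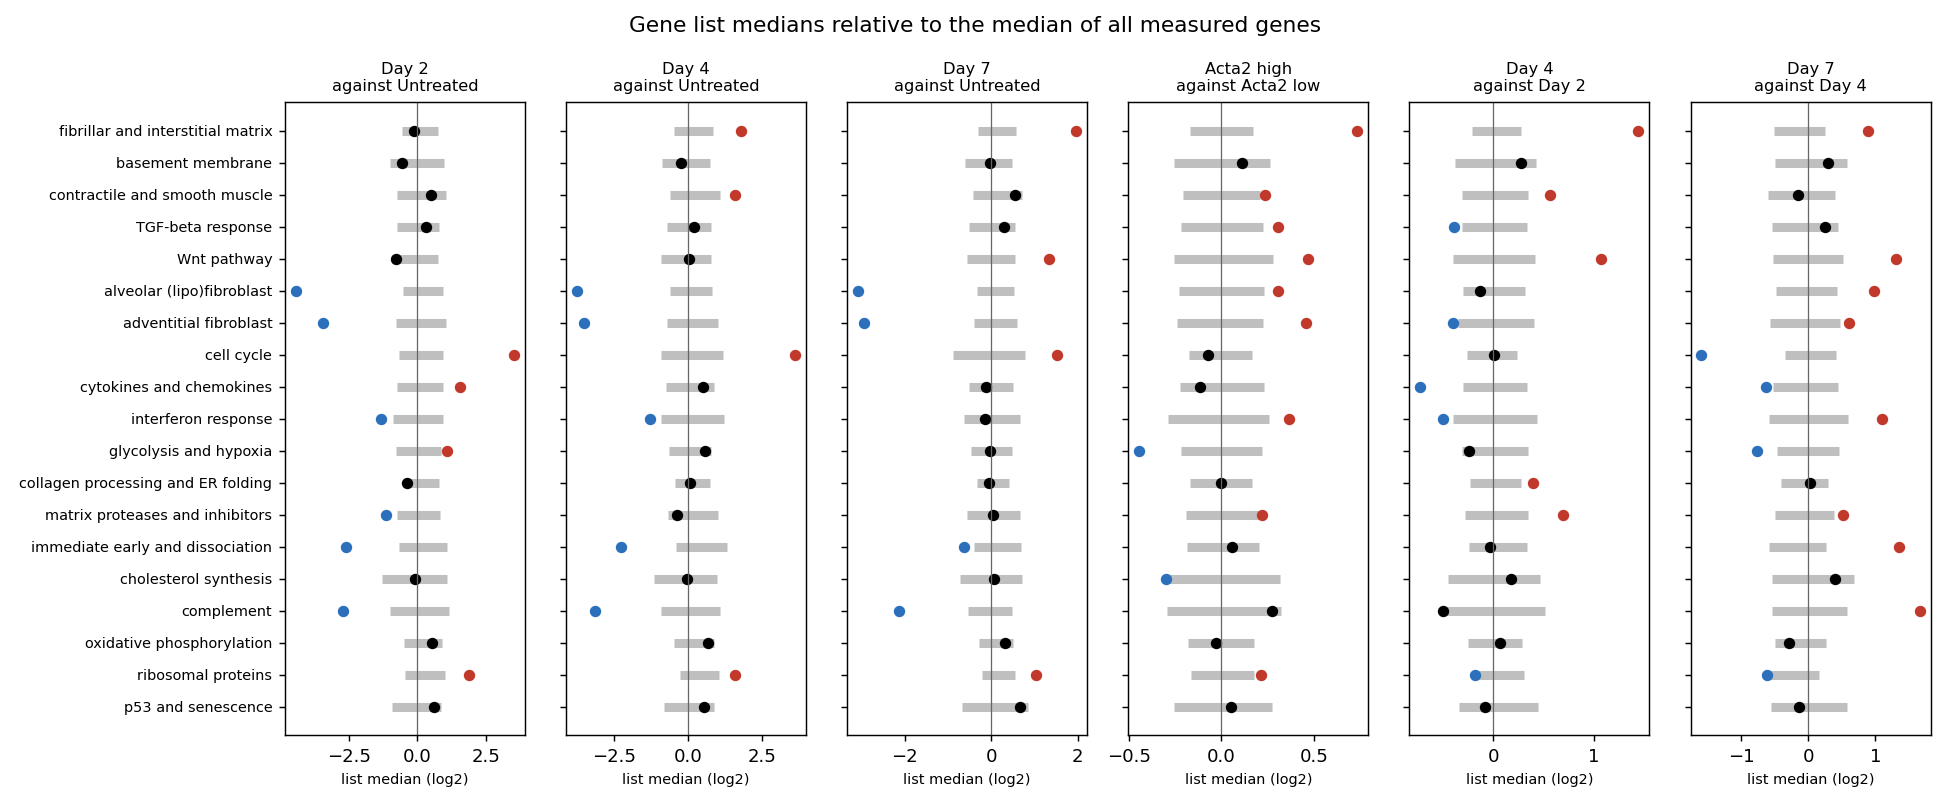
Median log2 difference of each gene list relative to the median of all measured genes, in the 6 comparisons (each panel has its own scale). Points are list medians, red or blue where called apart and black otherwise, and grey bars span the middle 95% of 10000 matched random lists; the matrix list lies 1.97 above the median gene for Day 7 and 0.74 above it for Acta2 high against Acta2 low.

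The Acta2 sort asked how transferred fibroblasts with high and low Acta2 reporter signal differ. Acta2 itself, which checks the labels, stood at 450.7 CPM in the Acta2 high library and 276.8 in the Acta2 low library, 1.80-fold higher relative to the median gene (1.68 to 1.92). Matrix genes were higher in Acta2 high cells, among them the microfibril protein gene Mfap5 (2.78-fold, 2.68 to 2.88) and Eln, elastin (2.50-fold, 2.34 to 2.66). The smooth muscle actin Actg2 was 2.59-fold higher (2.22 to 3.02), Igfbp7 2.49-fold (2.43 to 2.56) and Mgp, an inhibitor of calcification, 2.38-fold (2.37 to 2.40). No gene of 3998 measured was at least 4-fold higher; 6 were at least 4-fold lower, Krt8, Krt18, Slpi, Hmga2, Clu and Cck, of which Hmga2 and Clu are named here after their values were seen. The keratin Krt8 stood at 6.99 against 265.2 CPM, 34.4-fold lower (24.6 to 49.6), and the secreted protease inhibitor Slpi at 22.2 against 254, 10.4-fold lower (8.55 to 12.7). Cck, a peptide hormone gene, was 4.41-fold lower (3.76 to 5.19), Gch1 3.07-fold (2.53 to 3.75) and the chromatin protein gene Hmga1 3.01-fold (2.57 to 3.55).

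All 26 measured matrix genes were within 4-fold between the sorts, and their median lay 0.74 log2 above the median gene in Acta2 high (100th percentile), with 5 at least 2-fold higher and none 2-fold lower. Col1a1 and Col3a1 were 2.05-fold (2.01 to 2.08) and 1.90-fold (1.839 to 1.964) higher, Cthrc1 1.74-fold (1.69 to 1.80), Postn 2.70-fold (2.21 to 3.32) and Col8a1 2.62-fold (1.99 to 3.49), while Tnc was 1.28-fold lower (1.16 to 1.40). The contractile list, which holds the sorted gene Acta2, lay 0.24 above (98.57th percentile), with Myl9 2.08-fold and Tagln 1.964-fold higher. All 16 members were within 4-fold, and in CPM 9 were higher and 7 lower, Tpm1 (641.3 against 839.4) among the lower. Adventitial genes lay 0.46 above (99.99th; Igfbp4, Serpinf1, Ly6a, Cd248) and ribosomal protein genes 0.22 above (99.31st; Rps4x, Rpl32, Rps19, Rpl13). Other lists on the same side were Wnt (0.47 above, 99.92nd; Sfrp1, Nkd1, Fzd2, Nkd2), interferon (0.37 above, 99.68th; Ifi27l2a, B2m, Irf7, Psmb8), TGF-beta (0.31 above, 99.71st; Ctgf, Tgfb3, Ltbp2), alveolar (0.30 above, 99.54th; Mfap4, Limch1, Tcf21, Macf1) and proteases (0.22 above, 98th; Adamts2, Mmp2, Ctsk, Timp2), and each of these 5 calls was lost without the filter. Glycolysis and hypoxia genes were lower in Acta2 high, 0.44 below the median gene (percentile 0.0; Pkm2 1.65-fold, 1.51 to 1.80, with Slc2a1, Vegfa and Aldoa), and cholesterol synthesis genes lay 0.30 below (2.17th; Mvd, Insig1, Fdps, Cyp51), a call lost under median-ratio scaling (2.6th). Members of the TGF-beta list went both ways, with 8 of 12 higher in CPM in Acta2 high and 4 lower. Among the lower were Pmepa1, at 142.4 CPM against 424.7 in Acta2 low, and Smad7, at 25.4 against 48.1. The alveolar list had 7 members higher in CPM and 5 lower, and the protease list 9 and 7. Gli1 had 16 against 20 tags and Mki67 10 against 18, differences not detectable at this depth.

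Some genes on the marker lists of other cell types moved with the sort. Epithelial markers (3 measured, 0.01st percentile; Krt8, Krt18, Lyz1), mesothelial markers (4 measured, percentile 0.0; Krt8, Slpi, Krt18, C3) and endothelial markers (3 measured, 1.53rd; Plvap and Cav1, with Aqp1 at 20.6 against 20.8 CPM turning direction with the scaling) were lower in Acta2 high, and pericyte markers (3 measured, 99.61st; Postn, Lmcd1, Kcnj8) higher. Krt8 and Krt18 count in both of the first lists, and Postn is also a matrix gene. Of other endothelial markers, Pecam1 stood at 0 CPM in Acta2 low and 0.200 in Acta2 high, and Cdh5 at 0 in both. Of other pericyte markers, Rgs5 stood at 0.393 and 0 CPM and Cspg4 at 7.66 and 8.19. The endothelial and pericyte calls therefore do not show a difference in the share of those cells. The epithelial, endothelial and pericyte calls were lost without the filter, at the 7.55th, 27.5th and 87.3rd percentiles.

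**Figure D3:**
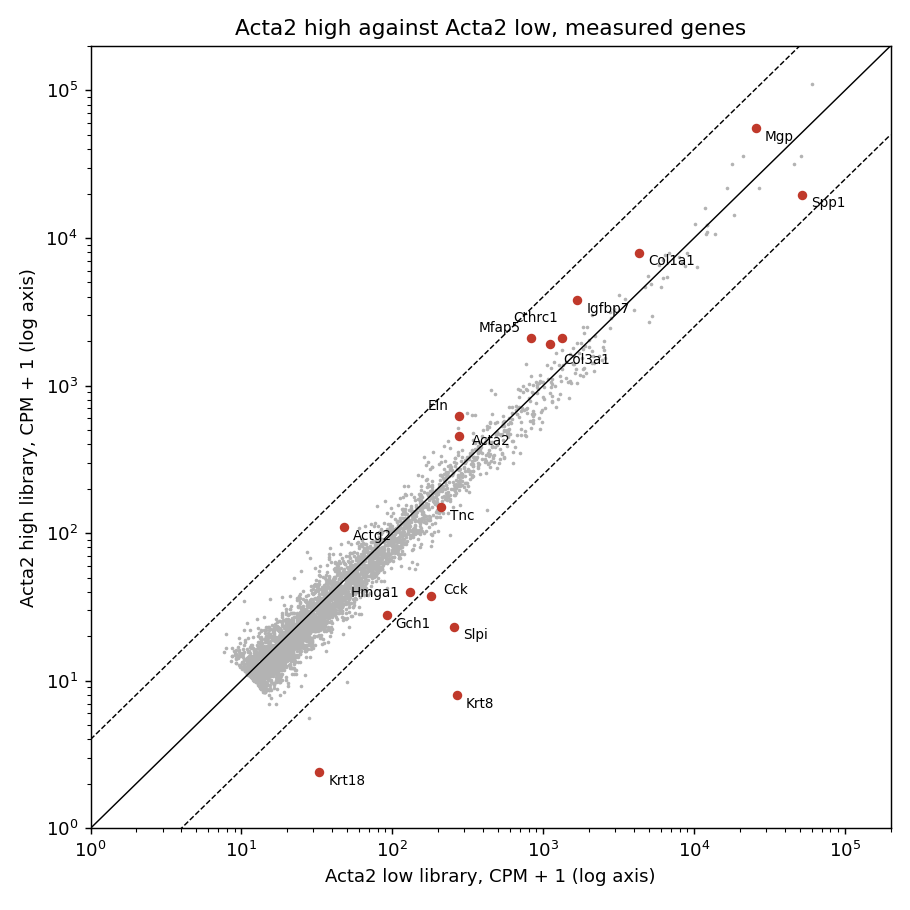
CPM + 1 of each measured gene in the Acta2 high library (vertical, log axis) against the Acta2 low library (horizontal, log axis). The solid line marks equal values and the dashed lines 4-fold differences; red points are anchor genes, the 5 most different genes each way, Krt18 and Spp1, and Krt8 lies at 6.99 against 265.2 CPM.

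Across the 3544 genes measured in both, the difference of Day 7 from Untreated and that of Acta2 high from Acta2 low had a Pearson r of 0.15 and a Spearman rho of 0.15; genes are not independent replicates, and no library is shared. This relation was fixed beforehand; 4 more of the same family were computed afterwards. The Pearson r across genes was -0.26 for Day 2 and -0.10 for Day 4 against Untreated, 0.37 for Day 4 against Day 2 and 0.31 for Day 7 against Day 4. Without the filter the r for Day 7 was 0.063.

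Of 132 placements of lists over the 6 comparisons, 69 were apart. The cut calls about 5% of lists of randomly drawn genes. That share is no baseline here, because members of a list may move together and the comparisons share libraries. Basement membrane, oxidative phosphorylation, and p53 and senescence lists were not apart in any comparison under the main rule, although the last reached the 99.4th and 99th percentiles for Day 2 and Day 4 against Untreated without the filter. The Hedgehog list never had 3 measured members. Gas1, measured in each comparison, stood at 48.8 CPM in Untreated and 9.39 to 33.7 in the other libraries. Smo was measured only for Day 7 against Day 4, at 14.5 against 7.42 CPM. Gli1 stayed under a mean of 10 CPM in every comparison, and Gli2 and Ptch1 stayed under 10 CPM in all 6 libraries. Markers of macrophages summed to 8.09 to 37.7 CPM per library, with Cd74 the most abundant in each (22.4 CPM at Day 7 against 2.70 at Day 4), those of other leukocytes to 0.799 to 2.75 CPM, and those of erythroid cells and platelets to 9.07 to 18.8 CPM, so these lists could not be placed.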

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

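All tests in this part were chosen after the results they measure were seen.

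Mmp2, which encodes a gelatinase, was singled out because its differences from Untreated have opposite signs at different time points. It stood at 363 CPM in Untreated, 67.2 at Day 2, 116 at Day 4 and 734.6 at Day 7. Its log2 difference from Untreated was 3.43 higher at Day 7 than at Day 2 and 2.65 higher at Day 7 than at Day 4. With 1 library per time point the difference between time points was not tested. Such a change of sign is not particular to Mmp2. From Untreated through Day 2 and Day 4 to Day 7, Mfap4 stood at 4106, 148, 421.5 and 8462 CPM. Igfbp4 stood at 542, 85.0, 164.1 and 1432 CPM.

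A set of 45 genes was at least 4-fold lower in both the Untreated and Day 7 libraries than in each of the other 4, where the next pair of libraries set 12 genes apart. Tags of interspersed repeats counted for single genes are a candidate explanation for part of it: of 41 members with a transcript to search, 43.9% held a tag sequence found in 100 or more genes, against a mean of 3.95% and a maximum of 17.1% in lists matched on transcript length. That is a share of genes, not of tags. Luc7l2 holds a tag found in 766 genes, but the most common tag of Zyg11b, the most abundant member, was found in 10 and that of Ogdh in 24. The search took every CATG of a transcript, not only the one nearest its 3' end. A few genes taking most of the Untreated and Day 7 counts would move every gene alike, and the median of all measured genes differed by only 0.31 log2 between Day 4 and Untreated. A batch holding the other 4 libraries cannot be told apart from a response of the cells, since the labels name no batch. The set also holds the cell cycle genes Ccnb1 and Rrm2 and the chemokine gene Ccl7, for which no biological explanation was tested.

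Krt8, Krt18 and Slpi were far higher in the Acta2 low library than in any other. Alveolar type II or club cells in that sort are argued against by their products Sftpc and Scgb1a1, whose sum had an upper 95% limit of only 3.26% of the Krt8 difference; other keratin-positive epithelial states were not tested. Mesothelial cells in that sort cannot be told apart from a change of keratin expression in fibroblasts. Their other markers were 1.67-fold higher in Acta2 low (1.28 to 2.20), with 8 of 11 higher, and 3.25-fold higher (2.22 to 4.86) without Aldh1a2, the 1 marker that was lower; Gpm6a stood at 5.30 against 0.200 CPM and Wt1 at 2.16 against 0. Untreated, however, held more of the 11 markers, 81.5 against 30.1 CPM, with Krt8 at 9.14 CPM.

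Of the 200 genes at least 4-fold lower at Day 2 than in Untreated, 113 were at least 2-fold higher at Day 7 than at Day 4, 5 at least 2-fold lower and 82 within 2-fold, and 103 were still at least 4-fold below Untreated at Day 7. Untreated cells or tags carried into the Day 7 library are argued against by abundant Untreated genes that stayed low, the fifth lowest, Hsd11b1, at 1.34% of its Untreated level, while Fos was at 28.8%. Across genes, the library most correlated with Untreated was Day 7 (Pearson r 0.81). A batch shared by Untreated and Day 7 cannot be told apart from a response of the cells, as the labels name no batch. A response to cell isolation that differs between libraries cannot be told apart from a change before isolation, because handling is not recorded per library. This holds for the 10 immediate early genes, with a median 2.04 log2 above that of all measured genes, and for the 190 others, 1.07 above, a median that the count of 113 already forces to be high. Some markers of other cell types had the same course from Untreated through Day 2 and Day 4 to Day 7, with Sftpc at 20.7, 5.51, 3.37 and 14.9 CPM, Scgb1a1 at 10.4, 3.56, 0.674 and 22.0, and Cd74 at 13.0, 4.05, 2.70 and 22.4, while Krt8 (9.14, 24.9, 16.4 and 6.49) and Cav1 (83.0, 212.5, 250.7 and 31.6) had another, and a share of other cells was not tested.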

How the results depend on the processing

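The 2-fold rule, the run without shared-tag genes and the run with floors were chosen after seeing the data. Of 132 list placements under each of 5 other settings (660 values), 605 kept their side and their call, 27 lost it, 21 gained it and 7 turned; with floors 67 lists were apart, against 69. No named gene past 4-fold turned, and the binomial test of the recovered tags and the pseudocount of 0.1 CPM moved no gene count by over 1.5 times. The binomial test removed no call in any comparison, so at this depth it is no check on the size rule. No paired analysis was possible because each group is 1 library. Depth limits low genes, with a floor of 3 tags at 0.486 to 0.675 CPM. The cause of the changes below was not tested, except that a 2-fold rule admits more genes by construction.

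Counts of higher or lower genes, each against its 4-fold count in the report, moved as follows. A pseudocount of 5 CPM gave 6 lower for Day 4 against Day 2 and 57 higher for Day 7 against Day 4. No filter gave 320 lower for Day 2, 627 higher and 346 lower for Day 4 and 375 higher for Day 7, all against Untreated, and 24 higher and 22 lower for Day 4 against Day 2. Median-ratio scaling gave 302 higher and 313 lower for Day 2 against Untreated, and 21 higher and 5 lower for Day 4 against Day 2. CPM without the 100 most abundant genes gave 522, 457 and 231 lower for Day 2, Day 4 and Day 7 against Untreated, 34 higher for Day 4 against Day 2 and 145 higher for Day 7 against Day 4. Without shared-tag genes, 51 were lower for Day 7 against Day 4.

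The 2-fold rule gave, higher and lower, 1655 and 441 for Day 2, 1046 and 549 for Day 4, 830 and 290 for Day 7, 22 and 36 for the Acta2 sort, 91 and 418 for Day 4 against Day 2, and 478 and 325 for Day 7 against Day 4.

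Lists that turned were interferon response, Day 2 against Untreated (71.3rd percentile with no filter, 58.7th without the 100 most abundant genes), TGF-beta response, Day 4 against Day 2 (72.5th and 65.4th), the list adventitial fibroblast, Day 4 against Day 2 (77.4th and 92.5th), and epithelial markers, Day 7 against Day 4 (44.3rd with no filter). For the time course against Acta2 sort, Day 7 against Untreated had an r of 0.0629 with no filter.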

Other observations

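The genes in this part were chosen after their values were seen, and none was tested for an explanation. Sox9, a regulator of cartilage development, went from 5.48 CPM in Untreated through 39.4 at Day 2 and 58.5 at Day 4 to 70.6 at Day 7, and stood at 69.1 in Acta2 low and 58.9 in Acta2 high. Scx, a tendon regulator, stood at 0.731, 0.972, 3.82 and 45.6 CPM, and at 19.6 in Acta2 high against 6.88 in Acta2 low. Fmod stood at 23.2, 3.40, 32.6 and 328.7 CPM.

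The cell cycle inhibitor gene Cdkn2a stood at 0.183, 0.810, 4.05 and 20.8 CPM in Untreated, Day 2, Day 4 and Day 7, and Cdkn2b at 0.548, 0.648, 9.67 and 31.1, while Cdkn1a peaked at Day 2 with 1846 CPM against 395.2 in Untreated. The metallothionein gene Mt2 stood at 631, 8447, 4063 and 208.6 CPM. Spp1 and Grem1, both most abundant at Day 7, were higher in Acta2 low than in Acta2 high: Spp1 at 51706 against 19670 CPM, 2.38-fold (2.36 to 2.40) relative to the median gene, and Grem1 at 91.5 against 41.1, 2.02-fold (1.71 to 2.39). Hmga2, a chromatin protein gene of embryonic tissue, had no tag in Untreated and stood at 48.9 CPM in Acta2 low and 8.79 in Acta2 high.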
